A study of Mus musculus with 18 samples.

How the data were processed

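The labels describe RNA from cells named RAW264.7, extracted with TRIzol, selected for poly(A), made into strand-specific libraries with dUTP and sequenced as paired ends on an Illumina instrument. The 18 libraries were assigned to 6 groups of 3 from the sample group in their labels, and the 3 libraries of a group are called biosamples there. Whether these were separate cultures or separate libraries of one culture is not given in the sources used here. The genome build in the labels is mm10, and the aligner, the quantifier and the annotation are not given in the sources used here.

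The gene table deposited by the authors holds estimated counts (expected counts) for 18397 genes, of which 10.9% of values were not whole at a tolerance of 0.001, so reads shared between features had been divided. It also holds TPM (tpm, transcript abundances scaled to a common sum), computed by the authors, and a normalized signal, which per the file headers is a normalized read count and equals the estimated count divided by a factor per library. The transcript table deposited by the authors holds estimated counts for 64855 RefSeq transcripts, 28562 of them curated and 36293 predicted, and 51.9% of its values were not whole. It was read only to check that each gene was the sum of its transcripts, within 0.05 counts. The signal columns were read only for their factors, and 44 columns of averages over groups were not used. Of the gene identifiers, 18257 (99.2%) matched the RefSeq annotation of GRCm38.p6, and 18237 of these had the same symbol. Positions are from that annotation. It has 13 protein-coding genes on the mitochondrial chromosome, and 0 genes of that chromosome were in the gene table.

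Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as the design, which left 12245, and libraries were scaled by TMM (factors from 0.968 to 1.03). A single quasi-likelihood model with a mean per group was fitted to the 18 libraries (glmQLFit, robust), and each comparison was a two-sided F-test with Benjamini-Hochberg adjustment over the genes tested. A gene was taken as changed at an adjusted p under 0.05. There were 11 comparisons: Stiff with Soft, each of mito and TW with its own matrix alone, the matrices within mito and within TW, mito with TW on each matrix, and the interactions of mito and of TW with the matrix. Log2 fold changes were those of the fit with its default prior count. A prior count of 2 was used only for the log2 CPM (library-scaled counts) behind the axes of variation and the check of replicate numbers as pairs. The adjusted p-values measure only the spread between these libraries, which may be technical: the common biological coefficient of variation was 0.0175, and the chi-square per degree of freedom between replicate libraries was 1.19 to 2.16, where counting error alone gives about 1. At so small a spread, small changes pass, and the number of changed genes of at least 2-fold is given beside the total.

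A set of 41 gene lists, 31 of pathways and 10 of cell type markers, was written from textbook knowledge. The lists, the tests, the groups, the rule for naming genes and the alternatives were fixed before the data were examined. The 39 lists with a tested gene were compared with the other genes by camera in limma 3.58.1 with a preset correlation of 0.01, and the 429 tests were adjusted together. The same tests were repeated with the correlation estimated from the data, and with fry, which asks whether a list's genes move one way and does not compare them with other genes. Counts adjusted over the list alone used only the genes of a list.

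Genes were named by a rule. It took, in the 5 comparisons with an untreated group, up to 8 higher and 8 lower genes of largest change with an adjusted p under 0.05, a mean of at least 5 CPM (library-scaled counts) and no overlap between the libraries of the groups, so that all 3 libraries of a group lay on one side. The other comparisons took up to 4 and 4, without the overlap condition for interactions. From each list came up to 4 members with the smallest adjusted p under 0.05, and Ddr2, Ptk2, Tiam1, Rhoa and Rac1 were always named. Levels of Csf1r, Adgre1, Lyz2, Ptprc, Epcam, Krt8, Krt18 and Col1a1 were always given, while the levels given of Cdh1, Vim, Prl2c2, Ccl3, Cd14, Tyrobp and Spp1 were chosen after their values were seen. Symbols of predicted genes were passed over. A few genes that the rule names and 1 of the lists are not reported here. Genes with few counts are given by their TPM in place of a fold, except for the interaction of TW and matrix of Tiam1, which is given with its counts.

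The tests were checked on simulated data with the design of these libraries and 12115 tested genes. Changed genes were drawn from those with an expected count of at least 50 per library. For Stiff+mito against Stiff, 90% of 50 genes simulated with a fold of 1.25 were called. With folds of 1.5 and 2, 98% and 100% were called, with 6 false among 200 calls. For the interaction of mito and matrix these shares were 72%, 92% and 100%, with 13 false among 195 calls. Comparisons simulated without change gave 0 calls, and of 100 unchanged lists 0 passed by camera and 5 by fry at a p under 0.05. Genes were simulated independently of each other, and 200 of them were changed, up and down alike. The check therefore does not cover changed genes of lower counts, lists of correlated genes or comparisons in which a large share of genes changes.

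Alternatives were RLE in place of TMM, library totals without factors, the Wald test of DESeq2 1.42.0, limma-voom, no filter beyond 1 count in total, a filter of 1 CPM in 3 libraries, a fit of only the groups compared, a block for the replicate number, and leaving out each library in turn. Other assignments of the libraries to groups were also tested, as all 10 splits for a pair of groups and 100 drawn reassignments for an interaction. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.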

Results

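RNA was sequenced in 18 libraries, 3 in each of 6 groups, all labelled as RAW264.7, a mouse macrophage line transformed by Abelson leukemia virus. The groups were cells on a soft matrix (Soft), cells on a stiff matrix (Stiff), and each matrix combined with an addition labelled mito (Soft+mito, Stiff+mito) or with a condition labelled TW (Soft-TW, Stiff-TW). The labels do not spell out mito or TW and give no stiffness values, and the series title names a transfer of mitochondria that depends on stiffness as the subject. The total of estimated counts per library ran from 16054637 to 16887244, and 11785 to 11909 genes per library had at least 10 counts. For counting error only, a count of 0 in a library allowed up to 3 counts, which for the median gene of at least 10 counts were 0.101 to 0.112 TPM and for shorter genes more. Across genes, log2(TPM + 1) of replicate libraries correlated with r = 0.998 in each of the 18 pairs, genes not being independent replicates. The leading axis of variation held 39.6% of the variance and separated the TW groups from the others, and the next held 26.8% and separated the matrices. For log2 fold changes, the value after ± is an approximate standard error, the size of the change divided by the square root of F. It can be too small where the change is large, so it is no exact measure of precision. Values after ± are standard deviations for TPM and standard errors for ratios, with n = 3 libraries per group. List tests are those of camera, and a list called higher or lower kept its call with an estimated correlation unless that adjusted p is given.

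The abundant cell type genes were not those of macrophages. Csf1r, the receptor for macrophage colony stimulating factor (gene 12978, chromosome 18, 61105572 to 61131139), lay between 0.0533 ± 0.0252 TPM in Soft and 0.83 ± 0.234 TPM in Soft-TW. Adgre1, which encodes the macrophage antigen F4/80, stayed at or under a group mean of 0.0833 ± 0.0513 TPM and Ptprc, the leukocyte antigen CD45, at or under 0.183 ± 0.0777 TPM. The keratins Krt8 and Krt18 of simple epithelia stood at 703 ± 12.1 and 307 ± 3.57 TPM in Soft, the intermediate filament gene Vim at 2166 ± 38.4 TPM, and Prl2c2 of the proliferin family, at 5882 ± 29.3 TPM, although close paralogs make its counts less certain. Epcam, an epithelial adhesion gene, and Cdh1, which encodes E-cadherin, had group means of at most 0.0333 ± 0.0577 and 0.16 ± 0.157 TPM, and Col1a1, a fibrillar collagen gene, of at most 3.85 ± 0.0551 TPM. Of 19 macrophage and myeloid markers in the table, 2 had a mean of 10 TPM or more over the 18 libraries, Lyz2 and Cd14. Cd14, a receptor for lipopolysaccharide, made up most of the markers' sum in Soft (27.6 ± 0.951 TPM) and Stiff (20.8 ± 0.795), and stood at 30.2 ± 0.589 in Soft-TW and 27.1 ± 1.58 in Stiff-TW. The summed abundance of these markers was 42.8 ± 0.472 TPM in Soft, 54.6 ± 1.88 in Soft+mito, 89.7 ± 1.57 in Soft-TW, 36.2 ± 2.71 in Stiff, 44.9 ± 1.68 in Stiff+mito and 59.8 ± 1.78 in Stiff-TW. For the marker lists of other cell types, 4 of 17 epithelial, 8 of 14 fibroblast, 5 of 9 osteoblast, 3 of 10 hepatocyte, 7 of 13 osteoclast, 1 of 7 melanocyte, 1 of 9 lymphocyte, 1 of 8 neutrophil and 0 of 9 endothelial genes were abundant enough to test. None of the 13 mRNAs encoded by mitochondrial DNA was in the table, so they were not analysed here.

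The comparison of Stiff with Soft asked which genes followed the matrix alone. Tenm4, a teneurin of the cell surface (gene 23966, chromosome 7, 96171244 to 96911093), rose with a log2 fold change of 3.01 ± 0.057 (10.7 ± 0.172 against 1.41 ± 0.188 TPM), and Fos, an immediate early transcription factor (gene 14281, chromosome 12, 85473890 to 85477274), with 2.54 ± 0.10 (15.9 ± 0.752 against 2.87 ± 0.778 TPM). Cth, which makes cysteine from cystathionine, rose by 1.71 ± 0.059 (57.6 ± 3.51 against 18.6 ± 1.88 TPM) and Aldh1l2, a folate enzyme of mitochondria, by 1.61 ± 0.024 (106 ± 0.578 against 35.9 ± 0.472 TPM). Cdsn, which encodes corneodesmosin, rose by 2.12 ± 0.040 (101 ± 3.80 against 24.5 ± 0.771 TPM), the peroxisomal oxidase gene Acox2 by 2.33 ± 0.12 and the carbonic anhydrase gene Car6 by 2.32 ± 0.094. Among the genes that fell were Sprr1a of the cornified envelope, at -2.13 ± 0.088 (17.1 ± 1.06 against 76.0 ± 2.70 TPM), the stromelysin gene Mmp10, at -1.97 ± 0.068 (11.8 ± 1.11 against 48.6 ± 0.247 TPM), and the stress-inducible Gadd45b, at -1.51 ± 0.075. Ddr2, a receptor tyrosine kinase for fibrillar collagen (gene 18214, chromosome 1, 169972307 to 170110836), rose by 1.02 ± 0.024 (80.1 ± 1.20 against 42.1 ± 1.44 TPM, adjusted p = 9.95e-65). Ptk2, which encodes focal adhesion kinase (gene 14083, chromosome 15, 73205102 to 73423820), had 0.021 ± 0.028 (adjusted p = 0.547), the GTPase gene Rhoa (gene 11848, chromosome 9, 108306160 to 108337943) 0.0002 ± 0.021 (adjusted p = 0.995) and the GTPase gene Rac1 (gene 19353, chromosome 5, 143505481 to 143528031) -0.032 ± 0.021 (adjusted p = 0.197). Tiam1, an exchange factor for Rac (gene 21844, chromosome 16, 89787111 to 90145600), was measured at 0.4 ± 0.0964 TPM in Stiff and 0.09 ± 0.0265 in Soft, from 1 to 27 counts per library over the 18 libraries.

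Genes of the integrated stress response, which includes amino acid synthesis and transport under Atf4, rose together on the stiff matrix, among them Trib3 (1.34), Asns (0.93) and Phgdh (0.79). In this list 24 of 24 genes rose and 0 fell (24 and 0 adjusted over the list alone, median 0.71, adjusted p = 1.53e-66). Mitochondrial chaperones and proteases moved the same way, with Lonp1 at 0.89 and Hspa9 at 0.55. Here 9 of 14 rose and 2 fell (9 and 2 adjusted over the list alone, median 0.23, adjusted p = 4.32e-06). The mitotic genes of the G2 and M phase list rose, including Tpx2 (0.61) and Ube2c (0.70). Of the 45 tested, 45 rose and 0 fell (45 and 0 adjusted over the list alone, median 0.43, adjusted p = 3.15e-29). Cholesterol biosynthesis genes fell, with Idi1 at -0.54 and Hmgcs1 at -0.39. In this list 0 of 24 genes rose and 22 fell (0 and 22 adjusted over the list alone, median -0.30, adjusted p = 3.6e-13). Cytosolic chaperones of the heat shock response also fell, with Cryab at -0.70 and Hsp90aa1 at -0.33. Here 1 of 15 rose and 13 fell (1 and 13 adjusted over the list alone, median -0.29, adjusted p = 1.19e-09). Lower on the stiff matrix were also glycolysis genes, with Eno1 at -0.70 and Ldha at -0.44, and hypoxia and HIF1 targets, although Ero1a, an oxidase of the endoplasmic reticulum, rose by 0.59. For glycolysis genes, 3 of 20 rose and 12 fell (3 and 12 adjusted over the list alone, median -0.16, adjusted p = 7.26e-07). Among 29 hypoxia targets, 5 rose and 19 fell (5 and 19 adjusted over the list alone, median -0.21, adjusted p = 0.00118).

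Inflammatory genes under NF-kB rose on the stiff matrix, with the chemokine gene Cxcl1 at 1.46 and the adhesion gene Vcam1 at 0.88. Of the 34 tested, 25 rose and 2 fell (25 and 3 adjusted over the list alone, median 0.34, adjusted p = 4.7e-05). Antigen presentation genes and interferon-stimulated genes were higher as well, with Tap2 at 0.44 and Ifih1 at 0.75. Of 14 antigen presentation genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone, median 0.35, adjusted p = 0.00125). For interferon-stimulated genes, 24 of 47 rose and 2 fell (24 and 2 adjusted over the list alone, median 0.29, adjusted p = 0.0356). The p53 targets were higher, with Gadd45a at 1.20, and so were fibroblast and mesenchymal markers, with the growth factor receptor gene Pdgfrb at 0.99 and the collagen gene Col3a1 at 0.76. Among 18 p53 targets, 13 rose and 3 fell (14 and 3 adjusted over the list alone, median 0.22, adjusted p = 0.000227). Of 8 fibroblast markers, 5 rose and 2 fell (5 and 2 adjusted over the list alone, median 0.34, adjusted p = 0.0107). Cytosolic ribosomal protein genes (median 0.21, adjusted p = 3.15e-11, adjusted p = 0.365 with an estimated correlation), NRF2 and antioxidant genes (median -0.059, adjusted p = 0.00426, adjusted p = 0.259 with an estimated correlation), epithelial markers (median -0.044, adjusted p = 0.0127, adjusted p = 0.0975 with an estimated correlation), and lipid efflux and LXR targets (median -0.092, adjusted p = 0.0247, adjusted p = 0.126 with an estimated correlation) lost their calls. Among alternative activation genes (median 0.15, adjusted p = 0.0253, adjusted p = 0.141 with an estimated correlation) the mean was -0.32, opposite in sign to the median and to the direction of the test, which was up.

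Of the lists that bear on mitochondria, nuclear OXPHOS subunits (adjusted p = 0.174), TCA cycle (adjusted p = 0.948), fatty acid oxidation (adjusted p = 0.786) and mitochondrial dynamics (adjusted p = 0.864) did not pass. Neither did mitochondrial ribosomal proteins (adjusted p = 0.982), whose median changed sign with library totals as the scale. Of those on adhesion and the matrix, extracellular matrix genes (adjusted p = 0.0649), YAP and TAZ targets (adjusted p = 0.25), endocytosis genes (adjusted p = 0.51) and mesenchymal transition genes (adjusted p = 0.948) did not pass. Genes of SRF, actin and focal adhesions (adjusted p = 0.751), lysosome genes (adjusted p = 0.261) and S phase genes (adjusted p = 0.982) also missed the threshold, each with a median that changed sign between scalings. The unfolded protein response (adjusted p = 0.982), immediate early genes (adjusted p = 0.508) and macrophage markers (adjusted p = 0.742) did not pass, nor did osteoclast (adjusted p = 0.901) and osteoblast genes (adjusted p = 0.948). Hepatocyte markers (adjusted p = 0.95) and the only tested melanocyte (adjusted p = 0.901), lymphocyte (adjusted p = 0.67) and neutrophil (adjusted p = 0.973) markers did not pass either. In all, 6588 genes changed (edgeR adjusted p under 0.05), 3564 higher and 3024 lower, of which 172 and 148 changed at least 2-fold. With library totals as the scale the share of changed genes that were higher went from 54.1% to 44.1%. The libraries of the groups did not overlap for 58.2% of the genes tested, where chance gives 10%.

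The comparison of Soft+mito with Soft addressed the mito addition on the soft matrix. Fos rose with a log2 fold change of 5.56 ± 0.064 (128 ± 4.68 against 2.87 ± 0.778 TPM), its relative Fosb with 4.30 ± 0.054 (82.8 ± 6.90 against 4.57 ± 0.382 TPM), and the zinc finger genes Egr1 and Klf2, both induced within minutes of growth or shear signals, with 2.33 ± 0.051 (118 ± 9.86 against 25.1 ± 0.825 TPM) and 2.53 ± 0.14. Dusp1, a phosphatase that acts on MAP kinases, rose by 2.09 ± 0.033 (215 ± 7.59 against 53.9 ± 1.3 TPM), and Ccn1, a matricellular gene, by 2.19 ± 0.029 (269 ± 11.8 against 63.0 ± 2.27 TPM). Cth fell, at -1.06 ± 0.087 (8.35 ± 0.787 against 18.6 ± 1.88 TPM), and the genes Cdsn and Tenm4 fell, at -1.08 ± 0.061 and -0.98 ± 0.10. Ddr2 fell, with -0.51 ± 0.027 (27.6 ± 1.71 against 42.1 ± 1.44 TPM, adjusted p = 8.68e-33), and Rhob, a GTPase gene of the immediate early kind, rose by 1.05 ± 0.039 (73.4 ± 1.67 against 37.8 ± 1.17 TPM). Rhoa (0.12 ± 0.021, 406 ± 2.23 against 399 ± 1.21 TPM) and Rac1 (0.12 ± 0.021, 392 ± 1.79 against 385 ± 8.52 TPM) had small positive values, the mean TPM of Rac1 differing by less than its spread. Ptk2 had 0.083 ± 0.027 (adjusted p = 0.0146) with mean TPM of 59.9 ± 1.93 in Soft+mito and 60.3 ± 1.08 in Soft, and Tiam1 was at 0.0433 ± 0.0252 and 0.09 ± 0.0265 TPM.

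Immediate early genes rose, with Jun at 1.15. In this list 19 of 26 genes rose and 1 fell (21 and 1 adjusted over the list alone, median 0.57, adjusted p = 1.06e-184). Inflammatory genes under NF-kB rose on balance, led by Socs3 (1.13), Ptgs2 (0.86) and Cxcl1 (0.84). Here 9 of 34 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.093, adjusted p = 1.21e-06). The summed abundance of macrophage markers went from 42.8 ± 0.472 to 54.6 ± 1.88 TPM in the same libraries. Genes of the integrated stress response fell, with Aldh1l2 at -0.84, Psph at -0.66 and Trib3 at -0.64, while Ppp1r15a, which is also induced early, rose by 0.69. Of the 24 tested, 2 rose and 18 fell (2 and 18 adjusted over the list alone, median -0.35, adjusted p = 1.13e-21). Glycolysis genes rose, with Ldha at 0.27, Eno1 at 0.26 and Aldoa at 0.22. In this list 15 of 20 genes rose and 1 fell (16 and 1 adjusted over the list alone, median 0.18, adjusted p = 7.6e-14). Hypoxia and HIF1 targets rose, with Bnip3 at 0.47 and the glucose transporter gene Slc2a1 at 0.28. Here 20 of 29 rose and 1 fell (20 and 1 adjusted over the list alone, median 0.19, adjusted p = 4.18e-09). Heat shock chaperones rose, with Hspb8 at 0.26 and Hspa8 at 0.19. Of the 15 tested, 14 rose and 0 fell (15 and 0 adjusted over the list alone, median 0.19, adjusted p = 2.07e-12).

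Nuclear genes for OXPHOS subunits were mostly higher, with Uqcr11 at 0.27 and Cycs at 0.18. In this list 55 of 76 genes rose and 0 fell (60 and 0 adjusted over the list alone, median 0.16, adjusted p = 2.56e-12, adjusted p = 0.173 with an estimated correlation). Cytosolic (median 0.16, adjusted p = 1.91e-15, adjusted p = 0.269 with an estimated correlation) and mitochondrial ribosomal proteins (median 0.10, adjusted p = 0.00157, adjusted p = 0.292 with an estimated correlation) likewise had positive medians and lost their calls. NRF2 and antioxidant genes (median 0.090, adjusted p = 1.16e-05, adjusted p = 0.0939 with an estimated correlation), with Hmox1 at 0.36, lysosome genes (median 0.074, adjusted p = 0.004, adjusted p = 0.0804 with an estimated correlation), p53 targets (median 0.034, adjusted p = 0.0302, adjusted p = 0.0614 with an estimated correlation) and TCA cycle genes (median 0.059, adjusted p = 0.0435, adjusted p = 0.283 with an estimated correlation) also lost their calls. YAP and TAZ targets (median -0.022, adjusted p = 0.00265, adjusted p = 0.0561 with an estimated correlation) had a median opposite to the test, which was up. Among lists that did not pass were fatty acid oxidation (adjusted p = 0.503), mitochondrial dynamics (adjusted p = 0.183), cholesterol biosynthesis (adjusted p = 0.241), interferon-stimulated genes (adjusted p = 0.899) and macrophage markers (adjusted p = 0.0696), and mitochondrial chaperones (adjusted p = 0.947), whose median changed sign with library totals. In all, 3274 genes changed, 1817 higher and 1457 lower, and 36 and 35 of them at least 2-fold. DESeq2 called 2113, and its count of at least 2-fold was 29 in place of 71, while a fit of only these groups gave 43. With library totals as the scale 38.3% of the changed genes were higher in place of 55.5%, so the balance between rises and falls depended on the scaling. For the median gene, 3 counts were 0.1011 to 0.1047 TPM in Soft+mito and 0.1098 to 0.1121 in Soft. Small changes in counts, of genes or of list medians, may therefore not hold in TPM, in which the lists were not checked. Libraries did not overlap for 37.6% of genes, against 10% by chance.

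The same addition on the stiff matrix raised Fosb by 4.74 ± 0.047 (158 ± 4.73 against 5.91 ± 0.723 TPM), Fos by 3.94 ± 0.041 (243 ± 3.32 against 15.9 ± 0.752 TPM), Egr1 by 2.77 ± 0.044 (248 ± 2.24 against 36.5 ± 1.79 TPM) and Klf2 by 3.49 ± 0.12. Dusp1 rose by 2.42 ± 0.031 (298 ± 1.77 against 56.0 ± 2.32 TPM), Ccn1 by 2.12 ± 0.025 (446 ± 8.92 against 103 ± 0.615 TPM), and Zfp36, which promotes the decay of cytokine mRNAs, by 1.84 ± 0.065. Car9, a cell surface carbonic anhydrase and HIF1 target, rose by 1.36 ± 0.044 (74.8 ± 3.70 against 29.3 ± 1.18 TPM). Genes that fell included Ddit3, the stress transcription factor CHOP, at -0.90 ± 0.043 (113 ± 8.89 against 213 ± 3.70 TPM), and the glutathione transferase gene Gsta1, whose close paralog Gsta2 makes its counts less certain, at -0.98 ± 0.12. Ddr2 fell, with -0.19 ± 0.022 (70.6 ± 1.69 against 80.1 ± 1.20 TPM, adjusted p = 2e-11), and Rhob rose by 1.59 ± 0.037 (102 ± 3.88 against 34.1 ± 1.95 TPM). Ptk2 (-0.023 ± 0.028, adjusted p = 0.565), Rhoa (0.032 ± 0.021, adjusted p = 0.253) and Rac1 (-0.027 ± 0.021, adjusted p = 0.351) did not pass, and Tiam1 was at 0.357 ± 0.0153 and 0.4 ± 0.0964 TPM.

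Immediate early genes rose here too, with Jun at 1.81 and Dusp6 at 1.45. Here 22 of 26 rose and 0 fell (22 and 0 adjusted over the list alone, median 0.77, adjusted p = 4.94e-232). Inflammatory genes under NF-kB rose on balance, with Socs3 at 1.38 and Nfkbiz at 0.97. Of the 34 tested, 10 rose and 5 fell (10 and 6 adjusted over the list alone, median 0.011, adjusted p = 0.000374). The summed abundance of macrophage markers went from 36.2 ± 2.71 to 44.9 ± 1.68 TPM beside them. The integrated stress response fell, with the cystine transporter gene Slc7a11 at -0.53 and Atf4 at -0.33, and mitochondrial chaperones and proteases fell, with Lonp1 at -0.28. For integrated stress response genes, 1 of 24 rose and 20 fell (2 and 20 adjusted over the list alone, median -0.27, adjusted p = 4.85e-23). Among 14 mitochondrial chaperone genes, 1 rose and 8 fell (1 and 9 adjusted over the list alone, median -0.13, adjusted p = 0.000777). Glycolysis genes rose, with Gpi1 at 0.45 and Gapdh at 0.25 (7589 ± 13.0 against 6429 ± 106 TPM), as did hypoxia and HIF1 targets, with Bnip3 at 0.57 and P4ha1 at 0.41. Of 20 glycolysis genes, 15 rose and 1 fell (15 and 1 adjusted over the list alone, median 0.18, adjusted p = 1.2e-12). For hypoxia targets, 19 of 29 rose and 3 fell (19 and 3 adjusted over the list alone, median 0.17, adjusted p = 5.6e-10). Extracellular matrix genes rose, with Thbs1 at 1.02, Sparc at 0.29 and the basement membrane collagen gene Col4a1 at 0.26. In this list 20 of 32 genes rose and 3 fell (21 and 3 adjusted over the list alone, median 0.18, adjusted p = 2.32e-08). YAP and TAZ targets, mesenchymal transition genes, with Vim at 0.51, and alternative activation genes rose as well. Among 24 YAP and TAZ targets, 11 rose and 1 fell (12 and 2 adjusted over the list alone, median 0.091, adjusted p = 1.19e-07). Of 12 mesenchymal transition genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.14, adjusted p = 0.000636). For alternative activation genes, 3 of 10 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.23, adjusted p = 0.000388). Cholesterol biosynthesis fell, with Hmgcs1 at -0.36 and Idi1 at -0.33, and so did S phase genes, with the replication helicase gene Mcm7 at -0.22. Among 24 cholesterol biosynthesis genes, 0 rose and 14 fell (1 and 14 adjusted over the list alone, median -0.12, adjusted p = 1.06e-05). Of 39 S phase genes, 0 rose and 25 fell (1 and 26 adjusted over the list alone, median -0.18, adjusted p = 1.14e-05).

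Antigen presentation (median 0.13, adjusted p = 0.0107, adjusted p = 0.0677 with an estimated correlation), osteoblast markers (median 0.26, adjusted p = 0.0199, adjusted p = 0.0598 with an estimated correlation), fibroblast markers (median 0.19, adjusted p = 0.0244, adjusted p = 0.0717 with an estimated correlation), NRF2 genes (median -0.091, adjusted p = 0.00527, adjusted p = 0.271 with an estimated correlation), lysosome genes (median 0.057, adjusted p = 0.0462, adjusted p = 0.214 with an estimated correlation) and cytosolic ribosomal proteins (median 0.067, adjusted p = 0.00789, adjusted p = 0.768 with an estimated correlation) lost their calls. Nuclear OXPHOS subunits (adjusted p = 0.188), mitochondrial ribosomal proteins (adjusted p = 0.252), TCA cycle (adjusted p = 0.862), fatty acid oxidation (adjusted p = 0.683), heat shock genes (adjusted p = 0.244) and macrophage markers (adjusted p = 0.191) did not pass. In all, 4099 genes changed, 1915 higher and 2184 lower, and 54 and 9 of them at least 2-fold. That count of 63 was 40 with DESeq2 and 99 with no filter beyond 1 count. Libraries did not overlap for 43.7% of genes, against 10% by chance.

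**Figure D1:**
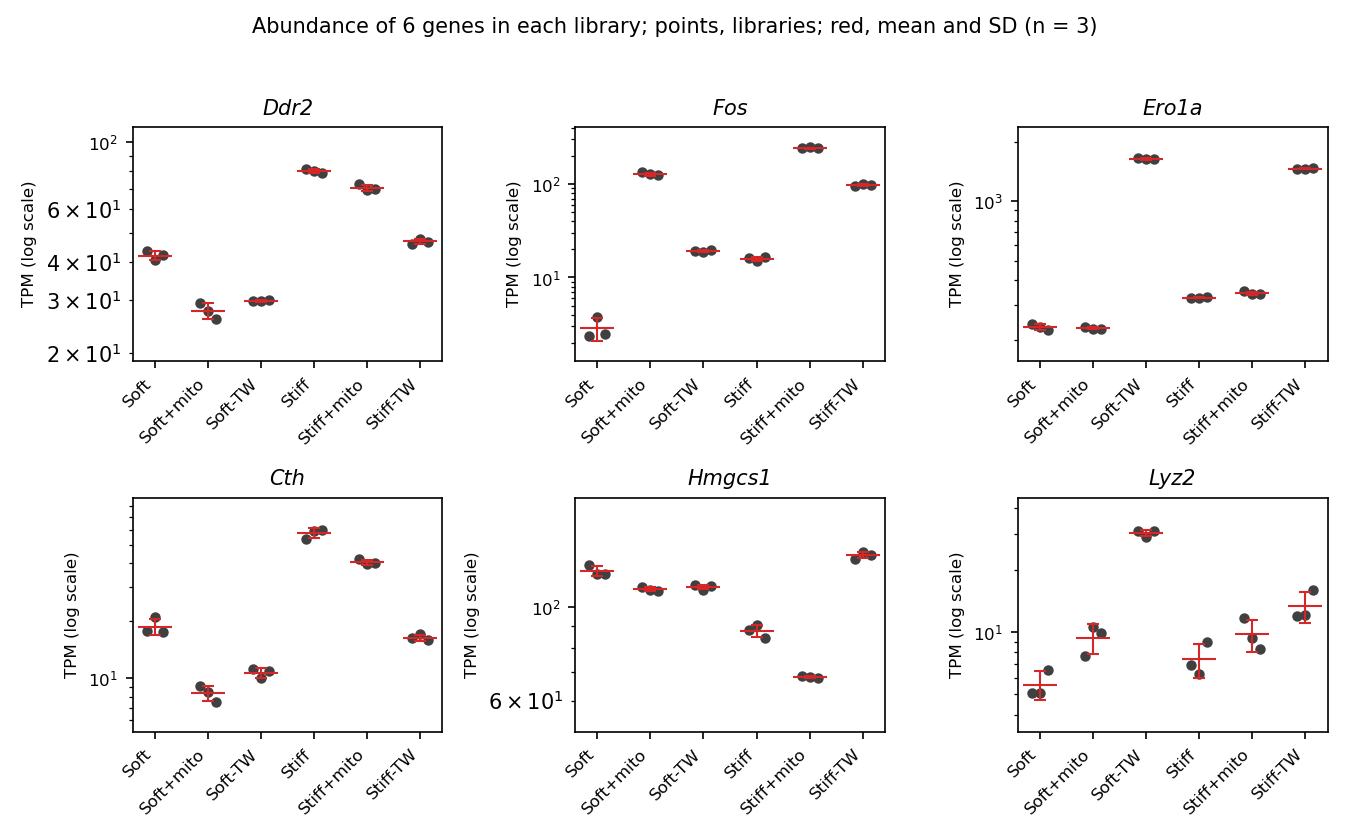
TPM on a log axis of Ddr2, Fos, Ero1a, Cth, Hmgcs1 and Lyz2 in the 6 groups, with points for libraries and the mean ± SD of 3 libraries in red. Fos stood at 2.87 ± 0.778 TPM in Soft and 128 ± 4.68 in Soft+mito, and Ero1a at 232 ± 7.98 in Soft and 1639 ± 11.9 in Soft-TW.

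The TW condition on the soft matrix was set against Soft. Ero1a, which forms disulfide bonds and is induced by hypoxia (gene 50527, chromosome 14, 45283087 to 45318572), rose by 2.93 ± 0.019 (1639 ± 11.9 against 232 ± 7.98 TPM). Ankrd37, another HIF1 target, rose by 3.58 ± 0.078 (128 ± 4.53 against 11.3 ± 0.417 TPM), the placental growth factor gene Pgf by 5.35 ± 0.15 (29.0 ± 1.57 against 0.920 ± 0.01 TPM), and the carbonic anhydrase gene Car12 by 2.80 ± 0.049. Irf7, a transcription factor of the interferon response, rose by 2.99 ± 0.15, Prdm1, a repressor of lymphoid and myeloid genes, by 3.62 ± 0.19, and Fos by 2.84 ± 0.10. The inducible nitric oxide synthase gene Nos2 stood at 4.26 TPM, from 0.03 in Soft where a library had at most 5 counts. Cryab, a small heat shock protein gene, rose by 2.07 ± 0.032 (589 ± 5.80 against 139 ± 8.28 TPM). The transferrin receptor gene Tfrc fell, at -0.99 ± 0.026 (49.7 ± 0.733 against 107 ± 3.49 TPM), as did Chac1, which degrades glutathione, at -1.04 ± 0.038, and the serine synthesis gene Psph, at -0.94 ± 0.049. Ddr2 fell, at -0.38 ± 0.027 (29.8 ± 0.177 against 42.1 ± 1.44 TPM, adjusted p = 6.56e-25), and Rhoa rose by 0.26 ± 0.021 (442 ± 2.97 against 399 ± 1.21 TPM, adjusted p = 5.08e-21). Rhob (0.66 ± 0.041) and Ptk2 (0.18 ± 0.027) rose, Rac1 fell little (-0.054 ± 0.021), and Tiam1 was at 0.137 ± 0.0289 and 0.09 ± 0.0265 TPM.

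Hypoxia and HIF1 targets rose, with Bnip3 at 1.85, Slc2a1 at 1.65 and Vegfa at 1.45. Here 25 of 29 rose and 3 fell (25 and 3 adjusted over the list alone, median 1.24, adjusted p = 1.14e-148). Glycolysis genes rose with them, with Eno2 at 2.50, Gpi1 at 1.04 and Gapdh at 1.00. Of the 20 tested, 19 rose and 0 fell (19 and 1 adjusted over the list alone, median 0.80, adjusted p = 8.62e-79). S phase genes fell, among them the helicase genes Mcm5 (-0.81) and Mcm3 (-0.72), and G2 and M phase genes fell, with Top2a at -0.27. For S phase genes, 1 of 39 rose and 36 fell (1 and 36 adjusted over the list alone, median -0.45, adjusted p = 2.86e-15). Among 45 G2 and M phase genes, 1 rose and 36 fell (1 and 38 adjusted over the list alone, median -0.19, adjusted p = 4.14e-05). Genes of the integrated stress response fell, with Phgdh at -0.71 and Slc7a11 at -0.65, although Aldh1l2 rose by 0.66. In this list 6 of 24 genes rose and 16 fell (6 and 16 adjusted over the list alone, median -0.35, adjusted p = 8.83e-08). Immediate early genes rose, with Junb at 1.12. Here 19 of 26 rose and 2 fell (19 and 2 adjusted over the list alone, median 0.28, adjusted p = 4.06e-10). Fibroblast and mesenchymal markers, with Prrx1 at 1.78 and Pdgfra at 1.05, and mesenchymal transition genes, with Snai1 at 0.77, were higher. Of 8 fibroblast markers, 4 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.25, adjusted p = 4.49e-08). For mesenchymal transition genes, 7 of 12 rose and 3 fell (7 and 3 adjusted over the list alone, median 0.24, adjusted p = 0.00949).

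Several groups of immune genes rose beside markers of macrophages. Of macrophage and myeloid markers, 9 of 11 rose and 0 fell (9 and 0 adjusted over the list alone, adjusted p = 0.00157, adjusted p = 0.0137 with an estimated correlation), and their summed abundance went from 42.8 ± 0.472 to 89.7 ± 1.57 TPM. Lyz2, which encodes lysozyme of myeloid cells (gene 17105, chromosome 10, 117277541 to 117282272), rose by 2.53 ± 0.13 (30.2 ± 1.06 against 5.59 ± 0.878 TPM) and Cd68, a lysosomal glycoprotein gene of macrophages, by 1.40 ± 0.13 (14.4 ± 0.818 against 5.90 ± 1.73 TPM). Ccl3, a chemokine gene of macrophages, stood at 7.97 ± 0.478 TPM against 0.203 ± 0.00577, and Tyrobp, an adaptor of myeloid receptors, at 3.00 ± 0.705 TPM where it was listed at 0 in Soft, 3 counts of this gene being about 1.08 TPM. Interferon-stimulated genes rose in the same libraries, with Dhx58 at 1.75 and Oas3 at 1.45. Of the 47 tested, 37 rose and 1 fell (37 and 1 adjusted over the list alone, median 0.63, adjusted p = 3.89e-07). NF-kB genes, with Lif at 1.3, and antigen presentation genes, with B2m at 0.56, rose as well. Among 34 NF-kB genes, 27 rose and 0 fell (28 and 0 adjusted over the list alone, median 0.64, adjusted p = 1.4e-12). Of 14 antigen presentation genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.47, adjusted p = 1.1e-06). Alternative activation genes rose, with the scavenger receptor gene Stab1 at 2.38 and Fn1, which encodes fibronectin, at 0.73. In this list 9 of 10 genes rose and 0 fell (9 and 1 adjusted over the list alone, median 0.62, adjusted p = 3.15e-11). Of its 24 members in the gene table only these 10 were tested. It shares Vegfa with the hypoxia list, and Fn1 with the lists of extracellular matrix and mesenchymal transition genes.

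Extracellular matrix genes (median 0.17, adjusted p = 0.0136, adjusted p = 0.0537 with an estimated correlation), with Mmp9 at 2.46, NRF2 genes (median -0.18, adjusted p = 1.03e-05, adjusted p = 0.091 with an estimated correlation), osteoclast genes (median 0.56, adjusted p = 0.0417, adjusted p = 0.0989 with an estimated correlation) and cytosolic ribosomal proteins (median 0.29, adjusted p = 1.13e-11, adjusted p = 0.356 with an estimated correlation) lost their calls. Nuclear OXPHOS subunits (adjusted p = 0.673), mitochondrial ribosomal proteins (adjusted p = 0.228), TCA cycle (adjusted p = 0.244), mitochondrial dynamics (adjusted p = 0.386) and cholesterol biosynthesis (adjusted p = 0.224) did not pass. In all, 6964 genes changed, 3538 higher and 3426 lower, and 306 and 50 of them at least 2-fold. With library totals as the scale the share higher went from 50.8% to 38.6%. Libraries did not overlap for 60.5% of genes, against 10% by chance.

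With TW on the stiff matrix, Ankrd37 rose by 4.73 ± 0.10 (99.6 ± 1.02 against 3.83 ± 0.788 TPM), Pgf by 3.89 ± 0.15, Car9 by 2.89 ± 0.037 (209 ± 2.04 against 29.3 ± 1.18 TPM) and Ero1a by 2.20 ± 0.018 (1464 ± 9.63 against 327 ± 2.60 TPM). Irf7 rose by 3.43 ± 0.14, and so did the interferon-stimulated genes Rtp4, by 2.93 ± 0.17, and Oas3, by 2.83 ± 0.10. Fosb rose by 3.24 ± 0.055, and Vim by 1.62 ± 0.019 (4217 ± 17.1 against 1426 ± 16.5 TPM). Tenm4 fell, at -2.62 ± 0.054 (1.65 ± 0.139 against 10.7 ± 0.172 TPM), as did Acox2 (-2.82 ± 0.13), Car6 (-1.56 ± 0.086) and Cth (-1.77 ± 0.060). Atf5, a transcription factor of the mitochondrial stress response, fell, at -1.73 ± 0.032 (83.4 ± 1.24 against 287 ± 10.9 TPM), and so did Rrp12, which takes part in ribosome assembly, at -1.80 ± 0.060. Ddr2 fell, at -0.74 ± 0.024 (46.9 ± 0.901 against 80.1 ± 1.20 TPM, adjusted p = 3.26e-53), and Rhoa rose by 0.29 ± 0.021 (446 ± 0.598 against 377 ± 6.58 TPM, adjusted p = 7.79e-25). Rhob (0.90 ± 0.041) and Ptk2 (0.14 ± 0.027) rose, Rac1 had 0.022 ± 0.021 (adjusted p = 0.344), and Tiam1 was at 0.0733 ± 0.0666 and 0.4 ± 0.0964 TPM.

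Hypoxia and HIF1 targets rose, with Bnip3 at 2.44 and Ndrg1 at 1.74. Here 25 of 29 rose and 1 fell (25 and 1 adjusted over the list alone, median 1.42, adjusted p = 3.7e-79). Glycolysis genes rose, with Pgk1 at 1.42, Gapdh at 1.3 and Aldoa at 1.18. Of the 20 tested, 18 rose and 1 fell (18 and 1 adjusted over the list alone, median 0.86, adjusted p = 5.06e-48). Genes of the integrated stress response fell, with Slc7a11 at -1.52, Trib3 at -1.20 and Phgdh at -1.03. In this list 2 of 24 genes rose and 21 fell (2 and 21 adjusted over the list alone, median -0.89, adjusted p = 3.39e-31). Mitochondrial chaperones and proteases fell, with Hspd1 at -0.98 and Lonp1 at -0.73. Here 2 of 14 rose and 11 fell (2 and 12 adjusted over the list alone, median -0.43, adjusted p = 1.6e-06). Cholesterol biosynthesis genes rose, with Fdps at 0.74 and Hmgcs1 at 0.64. Of the 24 tested, 23 rose and 1 fell (23 and 1 adjusted over the list alone, median 0.49, adjusted p = 9.75e-11). NRF2 and antioxidant genes fell, with Srxn1 at -0.94 and Txnrd1 at -0.67, and S phase genes fell, with Mcm2 at -0.70. For NRF2 genes, 5 of 28 rose and 22 fell (5 and 22 adjusted over the list alone, median -0.32, adjusted p = 5.6e-10). Among 39 S phase genes, 3 rose and 31 fell (3 and 31 adjusted over the list alone, median -0.34, adjusted p = 5.52e-05). Immediate early genes rose, with Jun at 1.43. In this list 21 of 26 genes rose and 2 fell (21 and 2 adjusted over the list alone, median 0.63, adjusted p = 3.61e-18). Extracellular matrix genes, with Thbs2 at 0.96, mesenchymal transition genes, with Twist1 at 0.77, and fibroblast markers, with Pdgfra at 1.38, rose. Of 32 extracellular matrix genes, 25 rose and 3 fell (25 and 3 adjusted over the list alone, median 0.39, adjusted p = 6.35e-05). For mesenchymal transition genes, 7 of 12 rose and 2 fell (7 and 2 adjusted over the list alone, median 0.29, adjusted p = 0.000374). Among 8 fibroblast markers, 6 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.46, adjusted p = 4.77e-07).

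Of macrophage and myeloid markers (adjusted p = 0.179), 9 of 11 rose and 0 fell (9 and 0 adjusted over the list alone). Cd68 rose by 1.60 ± 0.15 and Lyz2 by 0.94 ± 0.14, and the summed abundance of the 19 markers in the table went from 36.2 ± 2.71 to 59.8 ± 1.78 TPM, although the list did not pass. Beside them rose interferon-stimulated genes, with Dhx58 at 2.28 and Isg20 at 1.59, and NF-kB genes, with Tnfaip3, an inhibitor of that pathway, at 1.45. Of 47 interferon-stimulated genes, 38 rose and 4 fell (38 and 5 adjusted over the list alone, median 0.81, adjusted p = 9.56e-07). For NF-kB genes, 23 of 34 rose and 6 fell (23 and 6 adjusted over the list alone, median 0.32, adjusted p = 0.00204). Antigen presentation genes, with Tapbp at 0.76, and alternative activation genes, with Stab1 at 2.38 and Il4ra at 0.98, rose too. Among 14 antigen presentation genes, 9 rose and 3 fell (10 and 3 adjusted over the list alone, median 0.44, adjusted p = 0.000925). Of 10 alternative activation genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.79, adjusted p = 2.54e-05). LXR targets (median 0.31, adjusted p = 0.00636, adjusted p = 0.0679 with an estimated correlation), the unfolded protein response (median 0.23, adjusted p = 0.0124, adjusted p = 0.0671 with an estimated correlation), with Hspa5 at 0.76, G2 and M phase genes (median 0.14, adjusted p = 0.0339, adjusted p = 0.128 with an estimated correlation), mitochondrial (median -0.17, adjusted p = 0.0209, adjusted p = 0.463 with an estimated correlation) and cytosolic ribosomal proteins (median 0.20, adjusted p = 0.000558, adjusted p = 0.691 with an estimated correlation) lost their calls. Nuclear OXPHOS subunits (adjusted p = 0.763), TCA cycle (adjusted p = 0.411), fatty acid oxidation (adjusted p = 0.953), mitochondrial dynamics (adjusted p = 0.985) and heat shock genes (adjusted p = 0.223) did not pass. In all, 8521 genes changed, 4345 higher and 4176 lower, and 510 and 242 of them at least 2-fold. With library totals as the scale 44.4% of the changed genes were higher in place of 51%. Libraries did not overlap for 72.2% of genes, against 10% by chance.

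**Figure D2:**
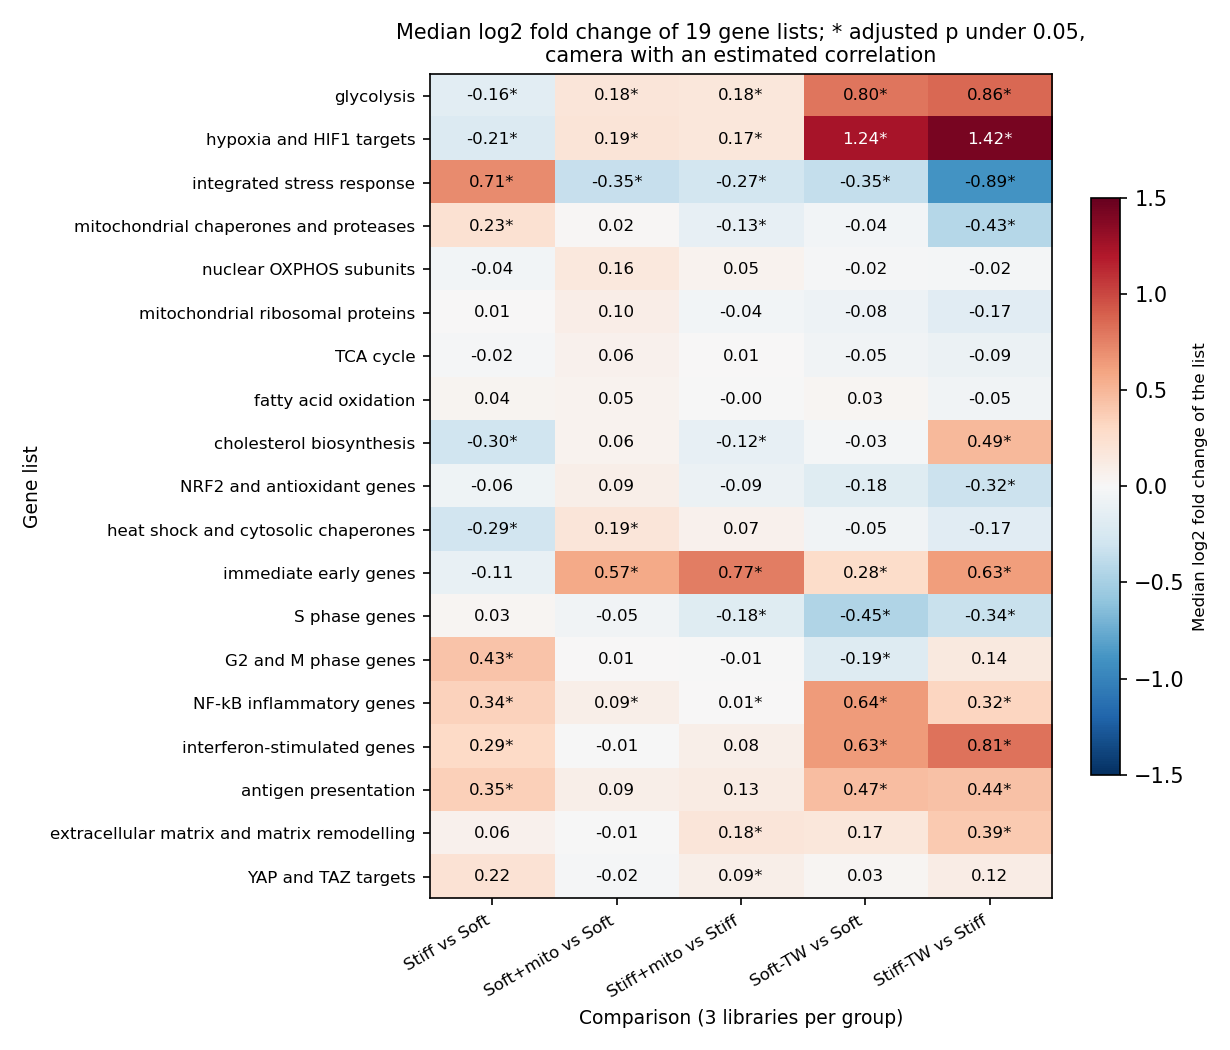
Median log2 fold change of 19 gene lists in 5 comparisons of 3 libraries per group, red for higher and blue for lower, with an asterisk where the adjusted p with an estimated correlation was under 0.05. The hypoxia list had medians of 1.24 and 1.42 with TW, and the integrated stress response 0.71 in Stiff against Soft and -0.89 in Stiff-TW against Stiff.

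Whether the mito response differed between the matrices was tested by the interaction, a positive value being a larger log2 fold change on the stiff matrix. Fos had -1.62 ± 0.11, its fold being smaller on the stiff matrix, while Car9 (1.23 ± 0.066) and Klf2 (0.96 ± 0.23) had larger ones. The libraries held 2.37 to 3.77 TPM of Fos in Soft and 123.81 to 133.01 in Soft+mito. They held 15.01 to 16.39 in Stiff and 240.59 to 246.5 in Stiff+mito. The low level in Soft thus enters the fold, and the rise in TPM was larger on the stiff matrix. Jun (0.67 ± 0.045) and Zfp36 (0.81 ± 0.094) also had larger rises there, and the immediate early list differed accordingly. Here 13 of 26 lay higher and 3 lower (15 and 3 adjusted over the list alone, median 0.26, adjusted p = 1.21e-06). Extracellular matrix genes, fibroblast markers and mesenchymal transition genes had higher values on the stiff matrix. For extracellular matrix genes, 16 of 32 lay higher and 2 lower (18 and 2 adjusted over the list alone, median 0.25, adjusted p = 6.68e-12). Among 8 fibroblast markers, 4 lay higher and 0 lower (4 and 0 adjusted over the list alone, median 0.33, adjusted p = 0.000326). Of 12 mesenchymal transition genes, 5 lay higher and 0 lower (5 and 0 adjusted over the list alone, median 0.091, adjusted p = 0.0012). Lower values were found for cholesterol biosynthesis, with Idi1 at -0.39, NRF2 genes, with Srxn1 at -0.38, heat shock genes and mitochondrial chaperones. For cholesterol biosynthesis genes, 0 of 24 lay higher and 14 lower (0 and 14 adjusted over the list alone, median -0.19, adjusted p = 7.51e-11). Among 28 NRF2 genes, 1 lay higher and 17 lower (2 and 18 adjusted over the list alone, median -0.21, adjusted p = 1.46e-14). Of 15 heat shock genes, 1 lay higher and 11 lower (1 and 11 adjusted over the list alone, median -0.16, adjusted p = 1.63e-06). For mitochondrial chaperone genes, 0 of 14 lay higher and 8 lower (0 and 8 adjusted over the list alone, median -0.13, adjusted p = 0.00012). For nuclear OXPHOS subunits (median -0.11, adjusted p = 1.4e-06, adjusted p = 0.359 with an estimated correlation) the call was lost with an estimated correlation. Glycolysis (adjusted p = 0.567), the sign of whose median changed with the scaling, hypoxia (adjusted p = 0.174) and integrated stress response genes (adjusted p = 0.982) did not pass. Ddr2 had 0.32 ± 0.035 (adjusted p = 6.32e-13), its fall being smaller on the stiff matrix. In all, 2888 genes differed, 1278 higher and 1610 lower, and 61 of them at least 2-fold. DESeq2 called 1815, of which 9 at least 2-fold, and with library totals as the scale 58.1% in place of 44.3% were higher.

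The interaction for TW asked the same of that condition. Cholesterol biosynthesis genes had higher values on the stiff matrix, with Acat2 at 0.90 and Fdps at 0.74. Of the 24 tested, 24 lay higher and 0 lower (24 and 0 adjusted over the list alone, median 0.56, adjusted p = 1.13e-43). Values for the integrated stress response were lower on the stiff matrix, with Aldh1l2 at -1.40 and Trib3 at -1.29, and so were those of mitochondrial chaperones. Among 24 integrated stress response genes, 0 lay higher and 20 lower (0 and 22 adjusted over the list alone, median -0.43, adjusted p = 3.45e-33). Of 14 mitochondrial chaperone genes, 1 lay higher and 10 lower (1 and 10 adjusted over the list alone, median -0.38, adjusted p = 1.21e-12). Values for G2 and M phase genes were higher on the stiff matrix, with Mki67 at 0.51. In this list 41 of 45 genes lay higher and 0 lower (41 and 0 adjusted over the list alone, median 0.33, adjusted p = 5.31e-22). Among single genes, Tenm4 had -3.20 ± 0.10 and Fosb 2.24 ± 0.12. The hypoxia list did not pass (adjusted p = 0.0966), with Ero1a at -0.73 and Bnip3 at 0.58, and in the glycolysis list (median 0.12, adjusted p = 0.0159, adjusted p = 0.17 with an estimated correlation) the call was lost, its mean being -0.034 where the median and the test were positive. Ddr2 had -0.36 ± 0.036 (adjusted p = 2.07e-15), its fall being larger on the stiff matrix. Macrophage markers did not pass (adjusted p = 0.73). In all, 4421 genes differed, 2004 higher and 2417 lower, and 186 of them at least 2-fold (121 with DESeq2).

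Set against Soft+mito, Stiff+mito had higher Tenm4 (3.48 ± 0.070, 7.54 ± 0.206 against 0.647 ± 0.0611 TPM), Cdsn (2.81 ± 0.048) and Cth (2.27 ± 0.073) and lower Gadd45b (-2.29 ± 0.070). Ddr2 was higher, at 1.35 ± 0.025 (70.6 ± 1.69 against 27.6 ± 1.71 TPM). The integrated stress response was higher, as were G2 and M phase genes, and cholesterol biosynthesis and heat shock genes were lower. For integrated stress response genes, 21 of 24 lay higher and 2 lower (21 and 2 adjusted over the list alone, median 0.76, adjusted p = 4.94e-39). Among 45 G2 and M phase genes, 45 lay higher and 0 lower (45 and 0 adjusted over the list alone, median 0.40, adjusted p = 1.77e-18). Of 24 cholesterol biosynthesis genes, 0 lay higher and 23 lower (0 and 23 adjusted over the list alone, median -0.50, adjusted p = 1.15e-20). For heat shock genes, 0 of 15 lay higher and 14 lower (0 and 14 adjusted over the list alone, median -0.47, adjusted p = 1.46e-14). Fibroblast markers were higher too, and macrophage markers, at 44.9 ± 1.68 against 54.6 ± 1.88 TPM in sum, did not pass (adjusted p = 0.738). Here 6 of 8 lay higher and 1 lower (6 and 1 adjusted over the list alone, median 0.62, adjusted p = 5.08e-05). In all, 7779 genes differed, 4004 higher and 3775 lower, 546 of them at least 2-fold, and with library totals as the scale 49.4% were higher in place of 51.5%.

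Between Stiff-TW and Soft-TW, Fosb (2.72 ± 0.051, 54.1 ± 0.762 against 8.39 ± 0.415 TPM), Fos (2.38 ± 0.045) and the death receptor gene Fas (1.34 ± 0.14) were higher on the stiff matrix, and Tfrc (-1.32 ± 0.034) was lower. Ddr2 was higher, at 0.66 ± 0.026 (46.9 ± 0.901 against 29.8 ± 0.177 TPM). Mitotic genes of the G2 and M phase list, extracellular matrix genes and cholesterol biosynthesis were higher, and heat shock genes were lower. Among 45 G2 and M phase genes, 45 lay higher and 0 lower (45 and 0 adjusted over the list alone, median 0.76, adjusted p = 1.25e-106). Of 32 extracellular matrix genes, 21 lay higher and 5 lower (21 and 6 adjusted over the list alone, median 0.38, adjusted p = 1.05e-09). For cholesterol biosynthesis genes, 19 of 24 lay higher and 0 lower (19 and 2 adjusted over the list alone, median 0.24, adjusted p = 1.49e-07). Among 15 heat shock genes, 0 lay higher and 14 lower (0 and 14 adjusted over the list alone, median -0.32, adjusted p = 4.59e-19). Fibroblast markers were higher too. Of the 8 tested, 8 lay higher and 0 lower (8 and 0 adjusted over the list alone, median 0.45, adjusted p = 8.72e-07). The summed abundance of macrophage markers was 59.8 ± 1.78 against 89.7 ± 1.57 TPM, with 0 of 11 higher and 7 lower (0 and 8 adjusted over the list alone), although the list did not pass (adjusted p = 0.062). In all, 6650 genes differed, 3378 higher and 3272 lower, 209 of them at least 2-fold (318 with no filter), and with library totals as the scale 42.9% were higher in place of 50.8%.

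Soft+mito was also set against Soft-TW. Fosb (3.29 ± 0.047), Fos (2.72 ± 0.043) and Dusp1 (1.79 ± 0.032) were higher with mito, and Pgf (-5.23 ± 0.14), Prdm1 (-3.73 ± 0.19) and Ankrd37 (-2.89 ± 0.070) were lower. Hypoxia and glycolysis genes were lower with mito, as were interferon-stimulated genes, while immediate early and S phase genes were higher. Of 29 hypoxia targets, 2 lay higher and 25 lower (2 and 25 adjusted over the list alone, median -1.10, adjusted p = 1.99e-110). For glycolysis genes, 1 of 20 lay higher and 19 lower (1 and 19 adjusted over the list alone, median -0.60, adjusted p = 1.93e-47). Among 47 interferon-stimulated genes, 2 lay higher and 38 lower (2 and 38 adjusted over the list alone, median -0.57, adjusted p = 3.39e-07). Of 26 immediate early genes, 17 lay higher and 6 lower (17 and 6 adjusted over the list alone, median 0.39, adjusted p = 1.46e-14). For S phase genes, 34 of 39 lay higher and 0 lower (34 and 0 adjusted over the list alone, median 0.42, adjusted p = 1.98e-11). Macrophage markers were lower with mito too (median -1.69, adjusted p = 0.0287, adjusted p = 0.0667 with an estimated correlation), a call lost with an estimated correlation, at 54.6 ± 1.88 against 89.7 ± 1.57 TPM in sum. Fibroblast markers were lower as well. In this list 0 of 8 genes lay higher and 7 lower (0 and 7 adjusted over the list alone, median -0.43, adjusted p = 3.09e-09). In all, 7330 genes differed, 3653 higher and 3677 lower, 428 of them at least 2-fold, and with library totals as the scale 55.1% were higher in place of 49.8%.

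On the stiff matrix, Stiff+mito had higher Tenm4 (2.10 ± 0.058), Acox2 (2.20 ± 0.14) and Klf2 (1.51 ± 0.091) than Stiff-TW, and lower Pgf (-3.74 ± 0.14), Ankrd37 (-3.17 ± 0.080) and Irf7 (-2.72 ± 0.12). Hypoxia, glycolysis, cholesterol biosynthesis and interferon-stimulated genes were lower with mito, and the integrated stress response and mitochondrial chaperones were higher. Among 29 hypoxia targets, 1 lay higher and 25 lower (1 and 25 adjusted over the list alone, median -1.13, adjusted p = 5.99e-97). Of 20 glycolysis genes, 1 lay higher and 18 lower (1 and 18 adjusted over the list alone, median -0.67, adjusted p = 3.19e-49). For cholesterol biosynthesis genes, 1 of 24 lay higher and 23 lower (1 and 23 adjusted over the list alone, median -0.62, adjusted p = 2.14e-27). Among 47 interferon-stimulated genes, 2 lay higher and 38 lower (3 and 38 adjusted over the list alone, median -0.63, adjusted p = 1.13e-08). Of 24 integrated stress response genes, 21 lay higher and 3 lower (21 and 3 adjusted over the list alone, median 0.72, adjusted p = 2.19e-21). For mitochondrial chaperone genes, 9 of 14 lay higher and 0 lower (9 and 0 adjusted over the list alone, median 0.27, adjusted p = 2.34e-05). The summed abundance of macrophage markers was lower with mito too, at 44.9 ± 1.68 against 59.8 ± 1.78 TPM, with 0 of 11 higher and 9 lower, although the list did not pass (adjusted p = 0.308). Fibroblast markers were lower on balance. Here 1 of 8 lay higher and 4 lower (1 and 4 adjusted over the list alone, median -0.21, adjusted p = 2.83e-07). In all, 7590 genes differed, 3700 higher and 3890 lower, 460 of them at least 2-fold, and with library totals as the scale 57.9% were higher in place of 48.7%.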

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

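The tests against chance, by reassigning libraries to groups, were chosen after the results were seen, while the interaction tests themselves were planned.

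The mito response differed between the matrices for 2888 genes in a test of the difference itself. Larger values on the stiff matrix were found for Car9 (1.23), Klf2 (0.96), Oas3 (0.90) and Ddr2 (0.32), in log2 units. Smaller values were found for Fos (-1.62), Moap1 (-1.43), Gsta1 (-1.37), Oasl1 (-0.99), Rac1 (-0.15), Ptk2 (-0.11) and Rhoa (-0.09). In TPM, Rhoa went with mito from 399 ± 1.21 to 406 ± 2.23 (soft) and from 377 ± 6.58 to 384 ± 1.77 (stiff). Ptk2 went from 60.3 ± 1.08 to 59.9 ± 1.93 and from 58.4 ± 1.1 to 57.7 ± 0.493. Neither gene showed the difference in TPM. Rac1 went from 385 ± 8.52 to 392 ± 1.79 and from 356 ± 2.66 to 348 ± 9.56, within the spread. The gap between counts and TPM was not particular to these genes. For the median gene, 3 counts were 0.1098 to 0.1121 TPM in Soft and 0.1011 to 0.1047 in Soft+mito. They were 0.1085 to 0.1089 TPM in Stiff and 0.1058 to 0.1089 in Stiff+mito. Small interaction values, of genes or of list medians, may thus hold in counts and not in TPM. Differences in list medians were not checked in TPM. List medians were higher on the stiff matrix for fibroblast markers (0.33), immediate early genes (0.26), extracellular matrix (0.25) and mesenchymal transition genes (0.09). They were lower for NRF2 genes (-0.21), cholesterol biosynthesis (-0.19), heat shock genes (-0.16), mitochondrial chaperones (-0.13), S phase genes (-0.09) and p53 targets (-0.04). Of 100 reassignments of these libraries to groups 1, the real one, gave as many genes, and the highest of the others gave 1880. Chance differences between cultures were not excluded, as the libraries of a group may come from the same culture. Reassigned groups also mix libraries of different groups, which widens the spread and lowers the calls, so these counts do not exclude chance. With the additive effects of matrix and mito removed first, 1 of 100 gave as many as the real 2660 and the highest other gave 7, with the same mixing of groups.

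The TW response differed between the matrices for 4421 genes. Larger values on the stiff matrix were found for Fosb (2.24), Sprr1a (2.03), the cadherin gene Cdh17 (1.44), Oas3 (1.38) and Rac1 (0.08). Smaller values were found for Tenm4 (-3.20), Car6 (-2.68), Tiam1 (-2.61, from 1 to 27 counts per library), Acox2 (-2.39), Cdsn (-2.07) and Ddr2 (-0.36). List medians were higher on the stiff matrix for cholesterol biosynthesis (0.56), G2 and M phase genes (0.33), immediate early genes (0.30), LXR targets (0.20), extracellular matrix (0.17) and mesenchymal transition genes (0.09). They were lower for the integrated stress response (-0.43), mitochondrial chaperones (-0.38), NF-kB genes (-0.22), NRF2 genes (-0.19) and p53 targets (-0.15). Chance was not excluded by plain reassignment, where 6 of 100 gave as many genes and the highest other gave 6645. Of the other reassignments as large, 5 kept or wholly exchanged the labels on 1 matrix, so that the large additive effect of TW entered the interaction. With the additive effects removed first, 1 of 100, the real one, gave as many as its 4545 genes and the highest other gave 106. These reassignments also mix libraries of different groups, which widens the spread and lowers the calls. With replicate libraries this close to each other, the test therefore does not exclude chance. As for mito, chance differences between cultures were not excluded.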

How the results depend on the processing

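All alternatives were planned, and 0 calls of named genes changed direction in those run for single genes, which left out library totals, while the balance of higher and lower genes in most comparisons and some list medians near 0 changed side with the scaling. The totals of changed genes stayed within 1.5 times the reported ones, except that DESeq2 called 2113 genes in place of 3274 for Soft+mito against Soft (2105 shared) and 1815 in place of 2888 for the interaction of mito and matrix (1808 shared). The cause was not tested. Counts of genes changed at least 2-fold moved more: with DESeq2 from 71 to 29 for Soft+mito against Soft, 63 to 40 for Stiff+mito against Stiff, 61 to 9 for the interaction of mito and 186 to 121 for that of TW, with only the groups compared from 71 to 43 for Soft+mito against Soft, and with no filter from 63 to 99 for Stiff+mito against Stiff and 209 to 318 for Stiff-TW against Soft-TW. Over the alternatives other than leaving out a library, totals ranged from 5345 to 6685 for Stiff against Soft, 2863 to 4193 for Stiff+mito against Stiff, 5795 to 7232 for Soft-TW against Soft, 7664 to 8608 for Stiff-TW against Stiff and 3273 to 4545 for the interaction of TW. Leaving out 1 library in turn gave 6002 to 6180, 3467 to 3633, 6443 to 6517, 8125 to 8183 and 4084 to 4266 for these, 2577 to 3038 for Soft+mito against Soft and 2455 to 2932 for the interaction of mito. Of the 429 list tests, 205 passed by camera, 130 of them with an estimated correlation, while fry passed 334 (202 shared), a test that does not compare a list with other genes. Of 1536 calls of named genes, DESeq2 kept 1490 and lost 41, and limma-voom lost 5. DESeq2 gave no adjusted p for 7 of the 1554 named results, called or not. Library totals as the scale moved the median of all genes by at most -0.0554 (log2). The replicate numbers were not taken as pairs: with a block for them counts were 6634 for Stiff against Soft and 3354 for Soft+mito against Soft. Omission of genes encoded by mitochondrial DNA was not run, as the table holds 0 of them, nor were the pseudocount and value filter planned for TPM, as counts were used.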

Other observations

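The tests of explanations and those of other splits were all chosen after the results were seen.

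Among abundant genes chosen after their values were seen, Spp1, which encodes the secreted matrix protein osteopontin, stood at 1507 ± 8.69 TPM in Soft, 1192 ± 22.8 in Soft+mito and 1181 ± 5.94 in Soft-TW (SD, n = 3). On the stiff matrix it stood at 2222 ± 25.5 TPM in Stiff, 2494 ± 40.6 in Stiff+mito and 1756 ± 15.3 in Stiff-TW. Vim, an intermediate filament gene of mesenchymal cells, stood at 2166 ± 38.4, 2504 ± 41.2 and 2965 ± 41.8 TPM in the same order on the soft matrix, and at 1426 ± 16.5, 2018 ± 54.6 and 4217 ± 17.1 TPM on the stiff one.

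Most macrophage markers were near 0 in libraries labelled as a macrophage line and were higher with TW, while Cd14 stood at 27.6 ± 0.951 TPM in Soft and 30.2 ± 0.589 in Soft-TW. A few wrongly labelled libraries among macrophage libraries were excluded, since Csf1r reached at most 1.1 TPM in any library. Summed markers of 4 absent cell types went from Soft to Soft-TW by a ratio of 0.829 ± 0.06, which argues against a rise of all nearly silent genes there. From Stiff to Stiff-TW they went by 1.12 ± 0.0512, which leaves a small rise open. The ratios of the macrophage markers were 2.09 ± 0.025 and 1.65 ± 0.0771. Their sum is mostly Lyz2, Cd68 and Cd14, which were not nearly silent, so these ratios do not bear on nearly silent genes. Of 19 markers, 2 had a mean of 10 TPM or more and 4 reached 1 TPM in Soft, where Krt8 stood at 703 ± 12.1 TPM. For these markers the values argue against RNA mainly of the labelled macrophage line. Which other cells gave the RNA was not tested. Lyz2 stood at 30.2 ± 1.06 TPM and Cd68 at 14.4 ± 0.818 TPM in Soft-TW. A small share of macrophage RNA in the TW libraries is a candidate source of the rise, as 17 markers had higher means with TW on both matrices. Induction of these genes in the main cells was not tested, and no sort or gate that would remove macrophages is named in the labels.

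Hypoxia targets and glycolysis genes were higher with TW on both matrices. Scaling was excluded, as the smallest medians over 3 scalings and both matrices were 1.18 for hypoxia targets and 0.75 for glycolysis. With TW, the gain in summed TPM on the stiff matrix over that on the soft one was 1.01 ± 0.012 for hypoxia targets. It was 1.31 ± 0.0134 for glycolysis and 0.504 ± 0.0413 for macrophage markers. These values argue against macrophage RNA with the same profile on both matrices as the source of the whole rise. As a source of a part it cannot be told apart, as no library of macrophages alone gives its profile. Per TPM of the hypoxia and glycolysis genes, the RNA gained held 1.56 ± 0.0376 (soft) and 0.613 ± 0.0726 (stiff) times the marker TPM of the matrix alone, a sum mostly of Cd14, but 8.45 ± 2.41 and 1.94 ± 0.497 times that of the 15 markers under 1 TPM there. Low oxygen or other conditions of the TW cultures, at a median of 1.24 in Soft-TW against Soft, cannot be told apart from the treatment that TW stands for, because the design has no culture with the same handling alone.

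Immediate early genes were higher with mito on both matrices. Scaling was excluded, as their smallest median over 3 scalings and both matrices was 0.54. On the soft matrix, the gain in summed TPM with mito over that with TW was 1.08 ± 0.0509 for immediate early genes. For macrophage markers it was 0.25 ± 0.0244. These values argue against macrophage RNA with the same profile under mito and TW as the source of the whole rise there. As a source of a part it cannot be told apart, for the same reason as above. The ratios of marker TPM were 0.513 ± 0.0554 (soft) and 0.258 ± 0.0645 (stiff) for all markers. They were 1.92 ± 0.934 and 0.615 ± 0.249 for those under 1 TPM, which rest on few counts. Time or handling before lysis cannot be told apart from the addition itself, since there was no handling control. Heat shock genes had a median of 0.07 in Stiff+mito against Stiff (adjusted p = 0.244), while in Soft+mito against Soft 14 of 15 rose (median 0.19, adjusted p = 2.07e-12).

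Other splits of the 6 libraries of a pair of groups were too few (10) for a share under 0.05, and the real split was the 1 with the most genes in each. Every other split mixes libraries of both groups, which widens the spread and lowers the calls, so these counts do not exclude chance. The highest other split called 0 genes where the real ones called 6588 (Stiff against Soft), 3274 (Soft+mito against Soft), 4099 (Stiff+mito against Stiff), 6964 (Soft-TW against Soft), 8521 (Stiff-TW against Stiff), 7779 (Stiff+mito against Soft+mito), 6650 (Stiff-TW against Soft-TW) and 7590 (Stiff+mito against Stiff-TW), and it called 1 where the real one called 7330 (Soft+mito against Soft-TW).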
